A study of Mus musculus with 4 samples.

How the data were processed

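Livers were digested, passed through a mesh and treated to lyse red blood cells, and single cells were made into libraries with a 10x Genomics 3′ kit, called version 3, per the labels' protocols. The dissociation and the lysis can set the shares of cells, and erythroid-like cells are those left after lysis. The deposited values are UMI counts per gene and barcode, written by Cell Ranger 6.0.1, per the file headers, with no normalization. The genome build is mm9 per the labels, and the gene annotation is not given in the sources used here. The reference in use was of another build, so no coordinates are given. Gene symbols are those paired with the identifiers in the deposited files, and 30934 of 31053 identifiers were found in a table of gene names. Whether the libraries were brought to 1 depth when they were joined is not stated.

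The matrix holds 38072 barcodes with suffixes 1 to 4, and no label, header or file pairs a suffix with a sample. The planned comparison of the tumor samples with normal liver was therefore not computed, the pool was taken as 1 sample, and each suffix is called a library. No week was inferred from the data. The weeks of the last sample differ between its label (10) and the series text (12).

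Barcodes were kept with at least 200 genes and 500 UMIs and under 20% mitochondrial UMIs, which removed 1838 barcodes for mitochondrial UMIs (30, 902, 107 and 799 in libraries 1 to 4) and 84 more for genes or UMIs. Doublets were scored within each library with the Scrublet method of scanpy 1.11.5, at an expected rate of 8%. The caller's automatic thresholds marked no barcode in libraries 2 and 4, so a score above 0.25 was used in all libraries, which removed 1336 barcodes (3.70%; 566, 136, 383 and 251 in libraries 1 to 4). The 34814 cells left held 121673850 UMIs with a median of 1766 per cell. Counts were normalised to 10000 per cell and logged, 2000 variable genes were scaled with a limit of 10, and 30 principal components and 15 neighbours fed Leiden clustering at resolution 1 with 2 iterations (igraph 0.11.9, scikit-learn 1.9.0), without batch correction. The members of the function lists and mitochondrial, ribosomal and haemoglobin genes were left out of the clustering genes, so no cluster was defined by a list on which it is compared.

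Of 24 clusters, 20 were named from marker lists and 4 stayed unnamed. A name rests on those lists alone and is written as X-like. The best class of a cluster was the one whose markers had the highest mean log2 ratio of the cluster's CPM to the lower quartile of the clusters' CPM, with 20 CPM added to each. Markers counted as detected in at least 10% of a cluster's cells, and a name needed 3 detected markers, at least 90 cells and no other class with more markers among the 10 leading genes. Under the rival rule, a class with more markers among the leading genes that was itself detected took the name. Clusters named from the markers of CD8 T cells are called T cell-like here, because no separate cluster of CD4 T cells formed, and the planned comparison of CD8 T cells with NK and CD4 T cells became 1 with NK cells. The filters, the clustering, the gene lists, the markers, the rule for named genes and most of the alternatives below were fixed before the data were examined. The doublet rate and score, the marker score (a first version, fold over all other cells, could not name hepatocytes), the 10% and 20 CPM settings, the rival rule, the minimum of 90 cells, the matching of clusters between settings (a Jaccard index of at least 0.3) and the way directions in single libraries are read were set after seeing the data.

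Counts were summed per class and given as CPM with exact Poisson 95% intervals. Shares have exact Clopper-Pearson intervals, and ratios of CPM have exact conditional binomial intervals (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, Python 3.11.15). Every interval covers counting error only, since no group has a replicate, and no test between groups was made. For a share, a count of 0 was taken to allow up to 3 counts, the 1-sided limit, which is 0.00862% of all analysed cells, while upper limits printed for genes with 0 UMIs are those of the wider 2-sided interval. In each comparison of classes the text names members of the function lists with at least 100 UMIs over both sides, a ratio of at least 2 in either direction whose interval excludes 1, and the same direction in every library with at least 20 cells of both sides, up to 30 genes per comparison and 8 per list, the largest ratios first. Across classes it names for each list the classes with the highest and second highest CPM of its members with at least 100 UMIs. Of 279 function genes 277 were in the matrix, and Aldoa and Cd244a were not found under those symbols. "Higher" and "lower" in a count of genes mean that a gene met the size and library conditions.

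The comparison code was tested on simulated Poisson counts drawn from the pooled profile of both real classes, with 50 genes changed at each of 4 ratios. Only genes with at least 200 UMIs over both classes were changed and scored. Genes between that number and the 100 UMIs needed for naming were thus not tested. The comparisons of hepatocyte-like clusters were not simulated. The profile and the ratios were the same in every library. Differences between libraries, spread beyond Poisson and RNA of other cells were thus absent, and the rates below hold for counting error alone. For macrophage-like against Kupffer cell-like cells (4761 genes) it recovered 98% of genes set at 2.5-fold, 100% at 4-fold, 84% at 0.4-fold and 74% at 0.25-fold, with 0 unchanged genes called and 95.6% of intervals holding the true ratio. For the T cell-like class against NK cell-like cells (4036 genes) it recovered 90%, 100%, 92% and 78% at those ratios, called 1 unchanged gene and had 94.9% of intervals holding the true ratio. For sinusoidal against vascular endothelial cell-like cells (4872 genes) it recovered 100%, 100%, 98% and 98%, called 0 unchanged genes and had 96.3% of intervals holding the true ratio.

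The alternatives fixed before the data were examined were a stricter filter (500 genes, 1000 UMIs, under 10% mitochondrial UMIs), doublets kept, Leiden resolutions of 0.5 and 2, function lists kept among the clustering genes, each library left out in turn, the mean of each cell's own CPM, cells thinned to 1000 UMIs in the same clusters (26180 cells are that deep), libraries at equal weight and a minimum of 20 UMIs. Alternatives chosen after seeing the data were the automatic doublet thresholds, no rival rule, no minimum of cells for a name, and counts under 3 set to 3 when the direction in a library is read. Figures were drawn with matplotlib 3.10.9.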

Results

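Single-cell RNA was measured in livers of a gene-induced mouse model of hepatocellular carcinoma (HCC), in a series that follows tumor development over time. There was 1 sample of normal liver at week 0 (HCC-NL) and 1 sample of tumor tissue each at week 4 (HCC-ES), at week 8 (HCC-MS) and at a last time (HCC-LS), which is week 10 in the sample's own label and week 12 in the series text. The count matrix joins 4 libraries, and no source used here pairs a library with a sample. It was therefore treated as 1 pooled sample, the weeks were not compared, and values of single libraries are given by library number with no test. Libraries 1 to 4 held 15593960, 49975828, 24012736 and 40617071 UMIs (counted RNA molecules), with median depths of 1304, 3131, 1318 and 2484 UMIs per barcode. After filtering, 34814 cells were analysed. There were no replicates, and every interval given is a 95% interval that covers counting error only.

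Hepatocyte-like cells made up 56.6% (56.1 to 57.2) of the analysed cells. Among endothelial cells, which line the vessels, sinusoidal endothelial cell-like cells held 8.76% (8.47 to 9.06) and vascular endothelial cell-like cells 3.98% (3.77 to 4.19). Macrophage-like cells held 5.79% (5.54 to 6.04) and Kupffer cell-like cells, the resident macrophages of the liver, 2.12% (1.97 to 2.28). The T cell-like class held 5.59% (5.35 to 5.84), neutrophil-like cells 2.0% (1.86 to 2.16) and natural killer (NK) cell-like cells 1.10% (0.990 to 1.21). Smaller classes were stellate cell- or fibroblast-like (0.979%), erythroid-like (0.957%), plasmacytoid dendritic cell-like (0.738%) and cholangiocyte-like cells (0.290%). The remaining 11.1% lay in 4 unnamed clusters, of which the largest, with 2401 cells, led with immunoglobulin genes and held markers of both B cells and plasma cells. Another, cluster 14, had 680 cells, and its markers scored highest for hepatocytes, with 10 detected. It had 1 monocyte marker and no hepatocyte marker among its leading genes, so the hepatocyte-like share leaves it out. Its median mitochondrial share was 10.4%.

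The classes were spread unevenly over the libraries. Sinusoidal endothelial cell-like cells held 22.9%, 2.09%, 5.52% and 4.40% of libraries 1 to 4, Kupffer cell-like cells 5.59%, 0.914%, 1.60% and 0.343%, and macrophage-like cells 0.792%, 15.2%, 2.54% and 5.75%. Hepatocyte-like cells held 43.1%, 51.0%, 65.3% and 65.7%. A minimum of 90 cells for a name, set after the data were seen, kept 1 cluster of 80 cells unnamed. Its markers scored highest for neutrophils, but it led with Peg10 and Afp beside neutrophil genes such as Camp and Retnlg, so that mixed barcodes cannot be set aside. It held 0.638% of library 2 and 0.343% of library 4 and no cell of the others. Without library 1, no Kupffer or cholangiocyte class was found, and the shares were 1.68% for vascular endothelial cell-like, 0.454% for plasmacytoid dendritic cell-like and 25.5% for unnamed cells. Without library 2 there was no Kupffer class and the erythroid-like share was 0.339%, without library 3 there was no cholangiocyte class and the vascular and unnamed shares were 6.79% and 3.04%, and without library 4 the NK share was 3.00%. At resolution 0.5 no Kupffer or vascular class was found and the macrophage-like share was 9.59%. The vascular share was 6.86% with doublets kept and 6.77% with automatic doublet thresholds, and the unnamed share 7.10% with those thresholds and 18.7% with the function lists kept in the clustering. Under the stricter filter the sinusoidal, neutrophil-like and unnamed shares were 3.58%, 1.27% and 0.109%, and with cells thinned to 1000 UMIs the sinusoidal share was 5.49%. That filter also gave plasma cell-like (6.05%), monocyte-like (2.22%) and conventional dendritic cell-like (0.863%) classes. A conventional dendritic cell-like class was found as well at resolution 2.0 (1.85%), with the function lists kept (1.12%) and with automatic doublet thresholds (1.12%). Without libraries 1 to 4 in turn it held 1.97%, 2.74%, 1.28% and 1.35%. A B cell-like class was found without library 3 (6.18%) and without library 4 (0.963%).

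**Figure D1:**
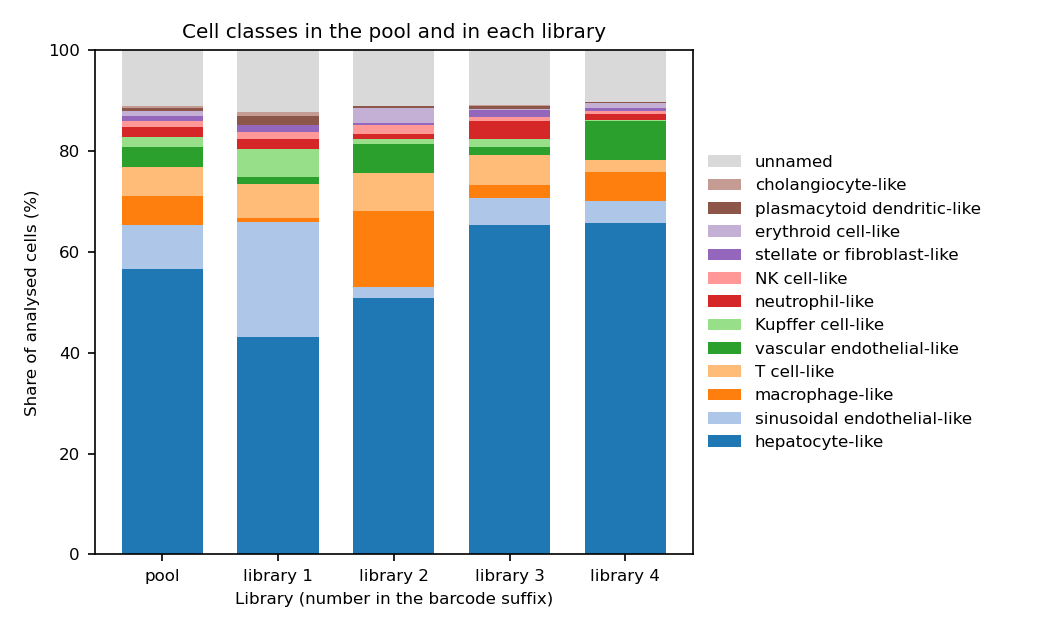
Share of analysed cells (percent) in each cell class, as stacked bars without intervals, for the pool and for each of the 4 unmapped libraries. Sinusoidal endothelial cell-like cells held 22.9% of library 1 and 2.09% of library 2, and macrophage-like cells 0.792% and 15.2%.

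The fixed gene lists were set across the 12 classes to ask which cells carried each function, counting the 271 members with at least 100 UMIs. Unnamed clusters were not ranked, and for 49 of the 271 members at least 1 of them stood above the leading class, among them Afp, H19, Gpc3, Myc and Fasn, 7 pericentral genes and all 6 genes of MHC class II presentation. The 7 pericentral genes each stood above it in cluster 14, whose markers scored highest for hepatocytes. Among named classes, hepatocyte-like cells had the highest level of all 10 pericentral genes, all 9 periportal genes and all 7 genes of bile acid synthesis and transport. Glul (ENSMUSG00000026473), the glutamine synthetase of hepatocytes around the central vein, reached 6104 CPM (6087 to 6120), where CPM are counts scaled to each class's total, and was 3.55-fold (3.45 to 3.65) above vascular endothelial cell-like cells. The periportal gene Ass1 (ENSMUSG00000076441), a urea cycle enzyme, reached 3963 CPM, 4.25-fold (4.09 to 4.42) above the next class. Baat, which conjugates bile acids, reached 127 CPM, 4.84-fold (3.32 to 7.35) above the next. Hepatocyte-like cells also led for 6 of 9 acute phase genes, such as Saa1 at 667 CPM and Orm1 at 729 CPM. They led for 5 of 8 glycolysis genes, such as Ldha at 1852 CPM, and for 5 of 8 genes of fatty acid synthesis, such as Fasn at 203 CPM. The iron-binding Lcn2 of the acute phase list was highest in neutrophil-like cells, at 4579 CPM (4454 to 4707). Of 11 fetal liver and carcinoma genes, 5 were highest in hepatocyte-like cells, among them H19 (ENSMUSG00000000031) at 2711 CPM and alpha-fetoprotein, Afp (ENSMUSG00000054932), at 183 CPM (181 to 186), 3.36-fold (3.01 to 3.77) above macrophage-like cells. The surface proteoglycan Gpc3 was highest in stellate cell- or fibroblast-like cells, at 69.3 CPM (54.4 to 87.0). The 10 liver cancer drivers were spread over 7 classes with at most 2 in any. Myc was at 177 CPM in vascular endothelial cell-like and 173 CPM in hepatocyte-like cells, a ratio of 1.02 (0.93 to 1.12). The order of the first and second class held in every library with enough cells for the genes named here, except Gpc3 (3 of 4) and Myc (2 of 4). Hepatocyte genes were counted in other cells as well, with Glul at 1119 CPM in the T cell-like class, and free RNA, remaining doublets and the cells' own expression were not told apart. The count of fetal and carcinoma genes led by hepatocyte-like cells was 3 without library 2.

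Among immune cells, 8 of 10 cytotoxic genes were highest in NK cell-like cells and 3 of 5 naive and memory genes in the T cell-like class. The lipid-associated macrophage list had 5 of 9 members highest in macrophage-like cells, with Gpnmb (ENSMUSG00000029816), a glycoprotein of lipid-laden macrophages, at 188 CPM (177 to 200), 10.0-fold (6.81 to 15.4) above Kupffer cell-like cells. Spp1 (ENSMUSG00000029304), osteopontin, was instead highest in cholangiocyte-like cells, at 28686 CPM, 256-fold (237 to 277) above macrophage-like cells. Libraries 1 to 4 held 74, 0, 24 and 3 cholangiocyte-like and 68, 1212, 249 and 486 macrophage-like cells, so this ratio mostly compares cells of different libraries. Neutrophil-like cells led for 5 of 11 inflammatory genes, with the neutrophil attractant Cxcl2 at 17938 CPM and the cytokine Il1b at 8256 CPM, 12.2-fold (11.8 to 12.7) above macrophage-like cells. Of 8 inhibitory receptor and exhaustion genes, 3 were highest in the T cell-like class (Pdcd1, Ctla4 and Tox). Pdcd1, the receptor PD-1 (ENSMUSG00000026285), stood at 61.0 CPM (54.3 to 68.2), 12.6-fold (5.34 to 39.0) above NK cell-like cells, but it was lower in library 1, at a log2 ratio of -1.52, and did not meet the library condition. Tox was higher in 2 of 4 libraries. Lag3 was highest in plasmacytoid dendritic cell-like cells, at 248 CPM. Plasmacytoid dendritic cell-like cells also led for 5 of 6 genes of MHC class II presentation, with Cd74 at 9071 CPM, against 17661 and 14456 CPM in clusters 0 and 5, which are unnamed. Cluster 5, with 691 cells, led with genes of myeloid granules, such as Mpo and Elane, and of MHC class II. Its markers scored highest for conventional dendritic cells of type 1, with 6 detected. It stayed unnamed because its leading genes held 1 platelet or megakaryocyte marker and none of that class. Plasmacytoid dendritic cell-like cells led for 5 of 6 genes of MHC class I presentation, with B2m at 1804 CPM, 1.04-fold (0.980 to 1.10) the next class. Leads were divided for the 8 checkpoint ligands, of which neutrophil-like cells led 3, and the 9 interferon response genes, of which macrophage-like cells led 3. They were divided as well for the 6 genes of alternative activation, of which Kupffer and macrophage-like cells led 2 each, and the 7 chemokine axis genes, of which the T cell-like class led 2. Several of these counts changed with the libraries taken, and clusters named conventional dendritic cell-like appeared in each of those runs, which then led for 5 or 6 MHC class II genes. The count of MHC class II in plasmacytoid dendritic cell-like cells was 0, 1, 0 and 0 without libraries 1 to 4, that of MHC class I was 2, 0 and 2 without libraries 2, 3 and 4, and that of alternative activation in Kupffer cell-like cells was 0, 0 and 1 without libraries 1, 2 and 3. Likewise the inhibitory receptor count was 1 without library 2, the inflammatory count 3 and the checkpoint ligand count 0 without library 3, the interferon count in macrophage-like cells 0, 1 and 1 without libraries 1, 2 and 3, and the chemokine count of the T cell-like class 1 and 0 without libraries 2 and 4.

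All 9 measured genes of matrix remodelling were highest in stellate cell- or fibroblast-like cells. Sparc (ENSMUSG00000018593), a matrix-binding protein, reached 3816 CPM (3699 to 3935) there, 2.37-fold (2.27 to 2.48) above vascular endothelial cell-like cells. Tagln (ENSMUSG00000032085), an actin-binding protein of contractile cells, reached 1385 CPM, 117-fold (82.7 to 170.2) above them. The chemokine Cxcl12 was also highest there, at 769.5 CPM, 13.5-fold above the next class. Of 9 angiogenesis genes, 4 were highest in vascular endothelial cell-like cells, among them Esm1 at 450.2 CPM (426 to 476), a gene of growing vessel tips, and 3 in sinusoidal endothelial cell-like cells. Proliferation genes were highest in erythroid-like cells, in 35 of 36 S phase genes and 47 of 51 G2 and M phase genes, with Mki67 (ENSMUSG00000031004), the Ki-67 antigen, at 477 CPM (450 to 505), 6.0-fold (4.80 to 7.60) above NK cell-like cells. Libraries 1 to 4 held 2, 240, 9 and 82 erythroid-like cells, so this lead could be read within libraries 2 and 4 only. Of 10 dissociation stress genes, 4 were highest in vascular endothelial cell-like cells, with Jun at 2793 CPM and Fos at 1622 CPM, which were above the next class in 0 of 2 and 2 of 4 libraries. Esm1 was above the next class in 3 of 4. The angiogenesis count of vascular endothelial cell-like cells was 2 without library 2, and their stress count 8 without library 3 and 2 without library 4.

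Macrophage-like cells were set against Kupffer cell-like cells to compare the macrophages of these livers with their resident kind. Genes of lipid-associated macrophages were higher in macrophage-like cells in 5 of 9 members, with log2 ratios of 4.28 (3.29 to 5.50) for Spp1, 3.59 (3.32 to 3.87) for Fabp5 (ENSMUSG00000027533), a fatty acid carrier, 3.33 (2.77 to 3.95) for Gpnmb and 2.34 (2.15 to 2.55) for the elastase Mmp12 (ENSMUSG00000049723). Inflammatory genes were higher in 5 of 11, with 1.65 (1.45 to 1.86) for the cytokine Tnf and 1.12 (0.93 to 1.32) for the chemokine Ccl3. Ptgs2, the cyclooxygenase of prostaglandin synthesis, had 491 UMIs against 1, a log2 ratio of 6.86 (4.37 to 12.16). Of 6 alternative activation genes 2 were lower in macrophage-like cells. These were Ccl24 (ENSMUSG00000004814), an eosinophil attractant, at -3.42 (-3.66 to -3.18) and the mannose receptor Mrc1 (ENSMUSG00000026712) at -1.49 (-1.64 to -1.35). Vegfa, the vessel growth factor, was higher at 2.78 (2.01 to 3.66). Isg15 and Mx1 were the 2 of 9 interferon genes that were higher, at 1.08 (0.96 to 1.20) and 2.34 (1.62 to 3.17). The glycolytic enzyme Hk2 was lower at -1.93 (-2.23 to -1.63). No member met the size and library conditions together among 6 genes of MHC class II, 6 of MHC class I, 17 of S phase or 22 of G2 and M phase. In all, 22 of 166 list members were higher and 4 lower by at least 2-fold with the same direction in the 4 libraries, and 77 passed on size without that condition. Of these 26, 19 had counts on both sides in every library, and 18 members were higher with counts under 3 set to 3. Hp and Saa3 of the acute phase list and Acaca of fatty acid synthesis were among the 22, below their levels in hepatocyte-like cells. Hp was highest in neutrophil-like cells. Free RNA cannot be set aside for these genes, nor can the cells' own expression. Hepatocyte lists were shifted in the same direction, with a median log2 ratio of 2.46 for 3 fetal liver and carcinoma genes and 1.47 for bile acid genes. The medians were 1.38 for pericentral, 1.19 for periportal, 1.24 for fatty acid synthesis and 0.67 for 7 acute phase genes. That of the lipid-associated list was 1.47. RNA of other cells thus cannot be set aside for this comparison, and its part in the ratios was not measured. Cells of the 2 classes came mostly from different libraries. Within single libraries the ratio ran from 1.05 to 2.79 for Fabp5, 0.28 to 3.07 for Gpnmb, 0.08 to 6.31 for Mmp12, 1.44 to 4.93 for Tnf and -1.19 to -0.70 for Mrc1. Automatic doublet thresholds gave 0.86 for Mmp12 and 1.89 for Gpnmb. Over all alternatives the lowest and highest values were 1.74 and 3.60 for Vegfa, 1.53 and 3.24 for Mx1, 3.56 and 4.39 for Spp1, 3.76 and 7.23 for Ptgs2, 1.01 and 2.04 for Tnf and -4.02 and -2.62 for Ccl24. Libraries at equal weight gave 1.72 for Fabp5, 1.39 for Gpnmb, 0.78 for Mmp12, 2.08 for Ccl3 and -0.98 for Hk2. Ptgs2 stood at 4.90 without library 3 and 4.77 without library 4, and neither library 1 nor library 2 could be left out, since no Kupffer class was then found.

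**Figure D2:**
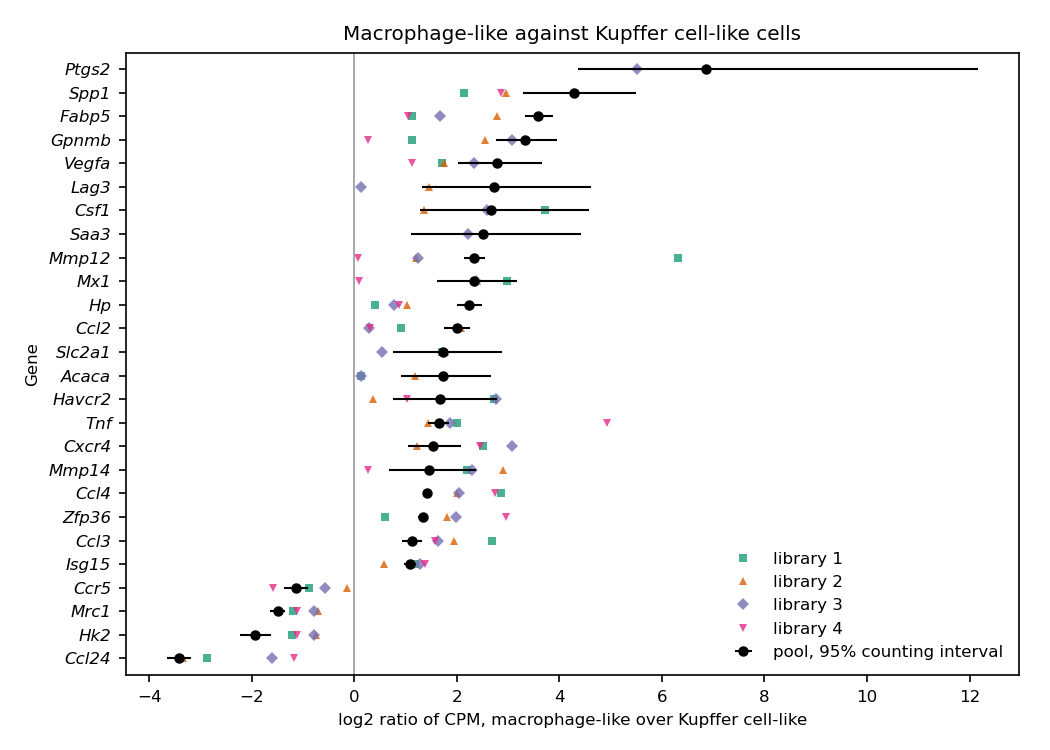
Log2 ratio of CPM, macrophage-like over Kupffer cell-like cells, for the named genes, with the pooled value and its 95% counting interval and 1 point for each of the 4 unmapped libraries with counts on both sides. Spp1 stood at 4.28 and Ccl24 at -3.42 in the pool.

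The T cell-like class was set against NK cell-like cells for genes of killing, memory and inhibition. Of 10 cytotoxic genes, 8 were lower in the T cell-like class. Among them were Gzma (ENSMUSG00000023132), a granzyme, by a log2 ratio of -5.54 (-5.64 to -5.45), the pore-forming Prf1 (ENSMUSG00000037202) by -3.24 (-3.55 to -2.95), Gzmb by -1.57 (-1.67 to -1.47) and the granule protein Nkg7 by -1.19 (-1.26 to -1.13). Gzmk (ENSMUSG00000042385) alone among them was higher, with 827 UMIs against 4 and a log2 ratio of 5.40 (4.04 to 7.28). Naive and memory genes were higher in 4 of 5, with the transcription factors Lef1 at 2.49 (1.90 to 3.14) and Tcf7 at 1.75 (1.25 to 2.31), the recirculation receptor S1pr1 at 1.91 (1.30 to 2.58) and the interleukin 7 receptor Il7r at 1.80 (1.51 to 2.11). Of 7 inhibitory receptor genes Ctla4 was higher, at 2.92 (1.78 to 4.39) with 223 UMIs against 6, and Cd160 lower, at -1.43 (-1.64 to -1.21). Interferon response genes were higher in 4 of 7, with Isg15 at 1.40 (1.12 to 1.69). The chemokine Ccl4 was lower at -1.74 (-1.83 to -1.66). No member of the 25 S phase, 35 G2 and M phase or 10 stress genes met the size and library conditions together. In all, 14 of 177 list members were higher (8 with counts under 3 set to 3) and 14 lower, and 34 passed on size without the condition on libraries. The 14 higher included Afp and Fabp5, which lay below their levels in hepatocyte-like cells and turned lower under 5 alternatives. Alternatives put Ctla4 between 2.44 and 5.53, Gzmk between 2.69 and 5.95, Tcf7 between 1.52 and 2.35 and Gzma between -6.15 and -4.65. Without library 2 the log2 ratios were -4.65 for Gzma, 2.69 for Gzmk, 2.45 for Il7r, 0.68 for Isg15 and -2.66 for Ccl4. Without library 4 they were -2.34 for Prf1, 1.58 for Lef1, 2.59 for S1pr1, 0.92 for Il7r, -0.63 for Ccl4 and -0.26 for Isg15, which turned its direction.

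**Figure D3:**
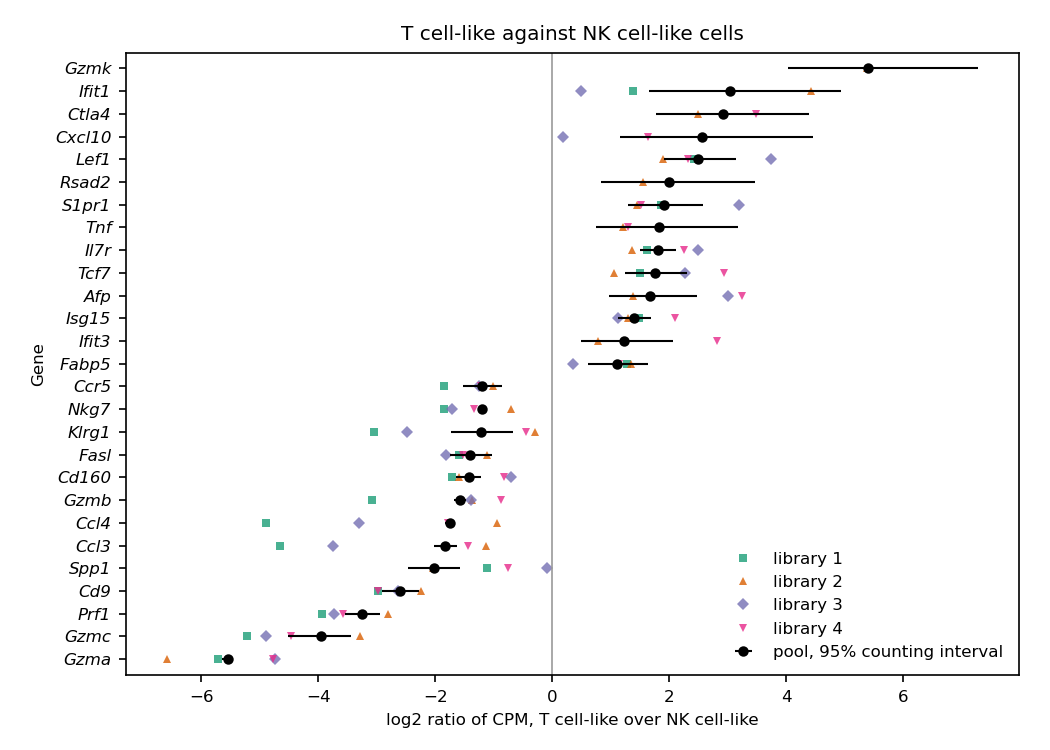
Log2 ratio of CPM, T cell-like over NK cell-like cells, for the named genes, with the pooled value and its 95% counting interval and 1 point for each of the 4 unmapped libraries with counts on both sides. Gzma stood at -5.54 and Lef1 at 2.49 in the pool.

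Sinusoidal endothelial cell-like cells, which line the liver's capillaries, were set against vascular endothelial cell-like cells. Genes of angiogenesis were lower in sinusoidal endothelial cell-like cells in 3 of 9 members and higher in none. These were Apln (ENSMUSG00000037010), a peptide of sprouting vessels, by a log2 ratio of -4.45 (-5.31 to -3.70), Cd34 by -2.87 (-3.23 to -2.53) and Plvap (ENSMUSG00000034845), which bridges endothelial openings, by -2.02 (-2.15 to -1.90). MHC class II genes were lower in 3 of 4, with Cd74 (ENSMUSG00000024610), the invariant chain, at -1.68 (-1.85 to -1.52) and H2-Eb1 at -1.37 (-1.67 to -1.07). The scavenger receptor Mrc1 was higher at 2.67 (2.51 to 2.83) and the chemokine Cxcl16 at 1.97 (1.69 to 2.26). The other 2 higher genes were Mmp14, at 1.31 (1.02 to 1.60), and Vsir, at 1.49 (1.05 to 1.96). Glycolysis genes were lower in 4 of 6, with Gapdh at -1.02 (-1.12 to -0.91) and Tpi1 at -1.88 (-2.08 to -1.69), and fatty acid synthesis genes in 3 of 7. Their levels were below those of hepatocyte-like cells, as for Hp, Ass1 and Gulo, so that free RNA cannot be set aside for them. The 10 dissociation stress genes moved as far as the angiogenesis list, with a median log2 ratio of -1.27 in each and Atf3 and Ier2 lower. The median mitochondrial share was 1.48% in the sinusoidal cluster, 4.63% in vascular cluster 11 and 1.49% in vascular cluster 18, so that the state of the cells cannot be set aside. In all, 4 of 149 list members were higher and 26 lower, and 75 passed on size without the condition on libraries. The vascular class joined cluster 11, with 6, 459, 106 and 638 cells in libraries 1 to 4, and cluster 18, with 112, 1, 57 and 5. Without library 1 the log2 ratios were 0.62 for Mmp14 and -0.99 for Tpi1, and those of Fasn, Acaca and Entpd1 turned to 0.05, 0.08 and 0.21. Without library 2 they were 1.96 for Mrc1, 1.00 for Cxcl16, 0.62 for Vsir, -1.08 for Cd74, -0.78 for H2-Eb1 and -2.69 for Apln. Without library 3 they were -3.77 for Cd34, -2.58 for Tpi1 and -5.53 for Apln, and Apln was at -5.52 without library 4. The count of higher genes was 9 without library 1. Across all alternatives the span was -5.55 to -2.69 for Apln, -4.54 to -1.85 for Cd34, -2.54 to -1.19 for Plvap, -2.46 to -1.08 for Cd74, -2.39 to -0.78 for H2-Eb1, 1.84 to 3.18 for Mrc1, 0.70 to 2.09 for Cxcl16, 0.39 to 1.67 for Vsir and -2.58 to -0.78 for Tpi1, and the lowest value of Mmp14 was 0.53.

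Hepatocyte-like cells fell into 8 clusters, each set against all other hepatocyte-like cells for fetal, zonation, metabolic and proliferation genes. Unnamed cluster 14, whose markers scored highest for hepatocytes, was not among them. No file labels cells as malignant, and each cluster drew on the libraries unevenly. Cluster 12, with 1844 cells and 13.8% of library 2, 7.49% of library 4, 1.03% of library 3 and 0.0699% of library 1, had 6 of 10 fetal liver and carcinoma genes higher. Afp had a log2 ratio of 3.96 (3.90 to 4.02) there, Golm1 2.99 (2.59 to 3.41), Gpc3 (ENSMUSG00000055653) 2.88 (2.72 to 3.03) and the stem cell antigen Prom1 2.79 (2.20 to 3.39). Of 10 pericentral genes 5 were higher (Axin2, Cyp1a2, Gulo, Lect2 and Slc1a2) and none lower. All 10 stress genes were higher too, with Jun at 2.42 (2.37 to 2.48), and the median mitochondrial share, 4.23%, was the highest of the hepatocyte-like clusters, so that the state of the cells cannot be set aside. Also higher were 39 of 51 G2 and M phase genes, with Mki67 at 2.98 (2.83 to 3.13), and 13 of 36 S phase genes. The lipogenic regulator Srebf1 stood at 3.24 (3.10 to 3.38), the bile salt export pump Abcb11 at 2.95 (2.86 to 3.04) and the gluconeogenic enzyme Pck1 at -2.46 (-2.52 to -2.40). Within libraries 2, 3 and 4 the ratio of Gpc3 was 2.59, 4.18 and 2.45 and that of Afp 4.10, 3.84 and 1.62. In all, 100 of 219 list members were higher and 14 lower in this cluster. Without library 4 the log2 ratios were 4.73 for Afp and -3.15 for Pck1, and without library 2 no cluster matched. The alternatives spanned 2.63 to 4.73 for Afp, 2.30 to 3.48 for Golm1, 2.25 to 4.23 for Prom1, 1.57 to 3.04 for Jun, 2.32 to 3.34 for Mki67 and -3.15 to -1.81 for Pck1.

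Genes of G2 and M phase were higher in 2 more hepatocyte clusters, and S phase genes in 1 of them. Cluster 1, with 2007 cells and 69.7% of them in library 2, had 23 of 36 S phase and 26 of 51 G2 and M phase genes higher, with log2 ratios of 2.28 (2.13 to 2.43) for the mitotic kinase Aurkb, 2.13 (2.02 to 2.24) for the nucleotide synthesis enzyme Rrm2 and 1.85 (1.75 to 1.95) for Cdk1. The fetal growth factor Igf2 (ENSMUSG00000048583) was higher at 1.13 (1.09 to 1.16) and the desaturase Scd1 at 1.11 (1.07 to 1.15). The periportal genes Sds and Cyp2f2 were lower at -3.96 (-4.32 to -3.62) and -2.43 (-2.86 to -2.04). Cluster 23, with 383 cells and 96.6% of them in library 3, had 24 of 51 G2 and M phase genes higher, with Ckap2 at 3.46 (2.95 to 3.93), but 0 of 36 S phase genes higher and 2 lower. The pericentral cytochrome Cyp1a2 stood at 2.37 (2.18 to 2.56). In it 7 of 9 periportal genes were lower, with Ass1 at -2.58 (-2.74 to -2.43). Its median depth was 792 UMIs and its leading genes included Lars2, AY036118 and Gm42418, and Gm42418 held 9.69% of the UMIs of library 3 against 3.08% to 6.27% in the others, so the quality of RNA cannot be set aside for cluster 23. In cluster 1, 55 list members were higher and 4 lower, and in cluster 23, which could be compared in library 3 alone, 32 and 23. In cluster 1 the log2 ratios without library 1 were 0.86 for Aurkb, 1.03 for Rrm2, 0.82 for Cdk1, -2.25 for Sds and -1.47 for Cyp2f2. Those without library 3 were -0.00, 0.33, 0.05, -2.12 and -1.40, and the 59 members higher or lower became 10 and 28. At resolution 2.0 the log2 ratios were 0.20 for Aurkb, 0.55 for Rrm2 and 0.29 for Cdk1, so these differences rest on the clustering and the libraries taken. Other alternatives put Igf2 between 0.56 and 1.92, Scd1 between 0.61 and 1.89, Sds between -5.19 and -2.12 and Cyp2f2 between -3.24 and -1.40 in cluster 1. In cluster 23 the log2 ratios without library 2 were 2.77 for Ckap2, 1.16 for Cyp1a2 and -1.59 for Ass1, and Ckap2 lay between 2.25 and 4.23 over all alternatives.

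Some pericentral genes were higher in clusters 19 and 20, 2 of 10 in cluster 19 and 3 of 10 in cluster 20, where 3 others (Cyp1a2, Cyp2c29 and Slc1a2) were lower. Cluster 12 had 5 higher, cluster 23 had 2 and cluster 1 had 1 (Gulo). In cluster 20, with 2833 cells and 59.5% of them in library 4, Glul had a log2 ratio of 1.63 (1.62 to 1.64), Oat (ENSMUSG00000030934) 1.81 (1.81 to 1.82) and Rgn 1.03 (1.02 to 1.05). With Gpnmb and Tox these are the 5 higher members, named here after their values were seen. Acute phase genes were lower in 8 of 9, inflammatory genes in 7 of 7, fetal and carcinoma genes in 7 of 10 and bile acid genes in 5 of 7. Gpc3 stood at -2.43 (-2.73 to -2.14), Afp at -2.86 (-2.97 to -2.76), Abcb11 at -2.47 (-2.65 to -2.30) and Srebf1 at -2.63 (-2.91 to -2.36). In cluster 19, with 3587 cells and 73.7% of them in library 4, Oat stood at 1.12 (1.11 to 1.13) and Glul at 1.01 (1.00 to 1.02), the only higher members. In it 7 of 9 acute phase genes were lower, with the iron hormone Hamp (ENSMUSG00000050440) at -3.67 (-3.79 to -3.56), but of the 7 only Hamp and Orm1 had counts on both sides in the 4 libraries. The cells that clusters 19 and 20 were set against include cluster 7, in which 8 of 9 acute phase genes were higher. Without library 3 the log2 ratios in cluster 19 were -1.27 for Saa1, -1.08 for Saa2 and -1.04 for Orm1. With all libraries they were -5.69, -5.97 and -2.15. Hamp, Saa3, Lcn2 and Orm2 stood at -3.18, -2.99, -2.06 and -1.52 without library 3. Within libraries 1 to 4 the ratio of Glul in cluster 19 was 3.43, 0.77, 2.52 and 0.26. In all, 5 members were higher and 71 lower in cluster 20, and 2 and 24 in cluster 19. Of these 76 and 26, 45 and 6 had counts on both sides in every library compared, and 49 and 4 members passed with counts under 3 set to 3. Without library 2 clusters 19 and 20 matched the same cluster, in which Afp stood at -1.19, Oat at 2.18, Glul at 1.97 and Hamp at -6.26. Without library 1 Hamp in cluster 19 stood at -5.04, and its 26 members higher or lower became 68, 74 and 137 without libraries 1, 2 and 3, while without library 4 no cluster matched it. Over all alternatives Glul in cluster 19 lay between 0.78 and 2.92, Oat between 0.61 and 3.64 and Hamp between -6.26 and -3.18. In cluster 20 Afp lay between -3.29 and -1.01, Gpc3 between -3.09 and -1.31, Abcb11 between -2.73 and -1.60 and Srebf1 between -3.17 and -1.59.

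Acute phase and periportal genes were higher in cluster 7, with 2366 cells and 96.9% of them in library 3. Of 9 acute phase genes 8 were higher, with log2 ratios of 5.93 (5.89 to 5.96) for the serum amyloid gene Saa1 (ENSMUSG00000074115), 4.26 (4.23 to 4.29) for Hamp and 3.54 (3.51 to 3.56) for Orm1. Of 9 periportal genes 6 were higher, with Cyp2f2 at 3.50 (3.37 to 3.64). Pericentral genes were lower in 6 of 10, with Glul at -4.58 (-4.64 to -4.53), and fetal and carcinoma genes in 5 of 10, with H19 at -6.04 (-6.18 to -5.91). Cluster 8, with 2969 cells and 97.2% of them in library 3, had 5 of 9 periportal genes higher, with the amino acid enzymes Sds at 2.78 (2.70 to 2.86) and Hal at 2.32 (2.20 to 2.43), and 8 of 10 pericentral genes lower, with Glul at -3.01 (-3.06 to -2.96). Cluster 6, with 3726 cells and 94.4% of them in library 1, had 8 of 10 stress genes lower, with Jun at -3.25 (-3.56 to -2.97). It also had 5 of 8 fatty acid synthesis genes lower, with Srebf1 at -3.05 (-3.73 to -2.45), and Afp at -7.11 (-8.17 to -6.23) from 10 UMIs. The median mitochondrial share of cluster 6 was 0%, the lowest of the hepatocyte-like clusters, so that the state of the cells cannot be set aside. In clusters 7 and 8 cell cycle genes, which have the longest lists, made up the largest groups of lower members by count. These were 21 of 36 S phase and 26 of 51 G2 and M phase genes in cluster 7 and 14 and 16 in cluster 8, against 7 and 2 in cluster 6. The list medians were no nearer to no change in cluster 6 than in the others. For S phase they were -2.63, -1.57 and -2.67 in clusters 7, 8 and 6, and for G2 and M phase -3.22, -1.62 and -3.57. Without the condition on libraries 172, 143 and 164 list members passed on size in clusters 7, 8 and 6. In all, 22 members were higher and 76 lower in cluster 7, 12 and 68 in cluster 8, and 1 (Lag3) and 55 in cluster 6. Only 44 of 98, 26 of 80 and 44 of 56 had counts on both sides in every library compared. With counts under 3 set to 3, 41 members passed in cluster 7, 24 in cluster 8 and 58 in cluster 6, and with the function lists kept in the clustering 150, 10 and 60. Each of these clusters could be compared within libraries 1 and 3 only, where the ratios were nearer to 0, at 1.58 and 2.73 for Saa1 and -1.49 and -3.25 for Glul in cluster 7, 1.40 and 0.65 for Sds in cluster 8 and -0.85 and -2.09 for Afp in cluster 6. In cluster 7 Saa1 stood at 9.20, 4.62 and 4.70 without libraries 1, 2 and 4, and Hamp at 6.13, 3.37 and 3.40. Orm1 stood at 4.18 without library 1, Cyp2f2 at 4.28 and 2.57 without libraries 1 and 2, and Glul at -3.80 without library 4. The 98 members higher or lower became 170 without library 1, where the direction was read in library 3 alone, while Glul in cluster 8 and Afp in cluster 6 stood at -4.00 and -6.05 without library 2. Libraries at equal weight gave 2.71 for Saa1, 1.55 for Hamp, 2.11 for Orm1, 2.36 for Cyp2f2, -2.64 for Glul and -4.87 for H19 in cluster 7, 0.77 for Hal and -1.24 for Glul in cluster 8, and -1.96 for Afp, -1.42 for Jun and -1.83 for Srebf1 in cluster 6. With the function lists kept, Sds, Hal and Glul in cluster 8 stood at 0.49, 0.71 and -1.07.

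**Figure D4:**
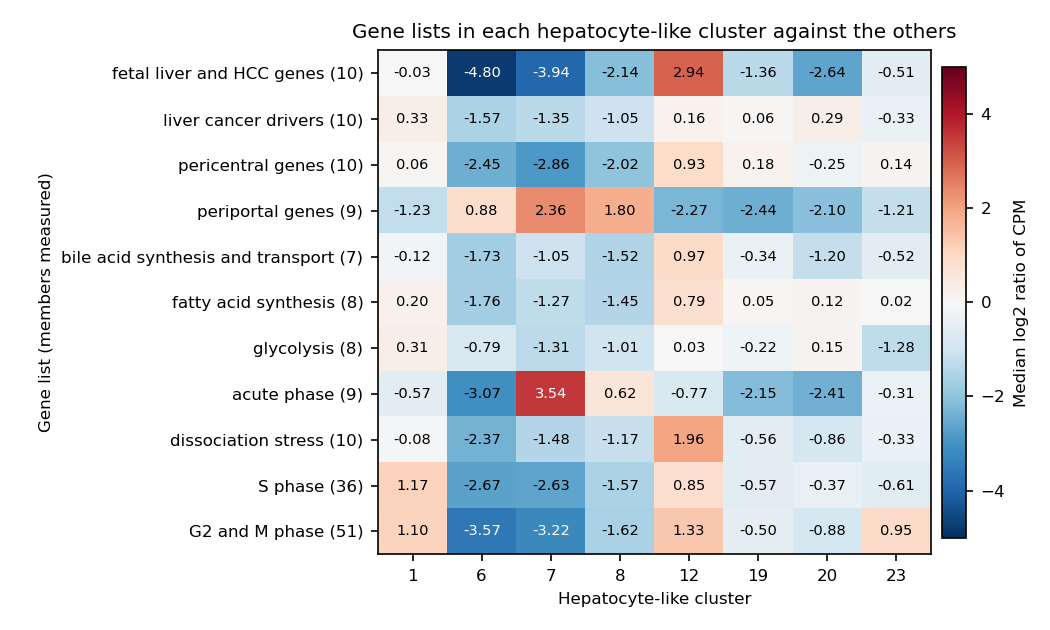
Median log2 ratio of CPM over the members of each gene list with at least 100 UMIs (colour), for each of the 8 hepatocyte-like clusters (columns) against all other hepatocyte-like cells. The fetal liver and carcinoma list had a median of 2.94 in cluster 12 and the acute phase list 3.54 in cluster 7.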

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

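The tests of all 3 weighed patterns were set down before their results were seen, but the patterns themselves were picked from the leading genes of the clusters, and the tests by depth were chosen after the ratios with thinned cells had been seen, which cannot bear on depth because the clusters stay the same. No biological explanation was tested, since the cells cannot be assigned to the weeks. The value below is listed only because RNA was counted above the limit that a count of 0 allows in barcodes left out of the analysis, and it lies below the 183 CPM of Afp in hepatocyte-like cells.

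Barcodes left out for mitochondrial UMIs held Afp, the fetal liver protein, at 144 CPM (133 to 155) over 1838 barcodes, with 139, 108 and 156 CPM in libraries 2 to 4, beside Alb at 6088 CPM. In library 1 there were 0 UMIs of Afp in 30 barcodes, which allows up to 115 CPM, above the value in library 3.

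Glul and Oat were higher in hepatocyte-like clusters 19 and 20 than in other hepatocyte-like cells. A difference between libraries is argued against as the whole source by the log2 ratio of Glul within libraries, whose lowest value was 1.17 (1.16 to 1.19) in library 4, against 3.63, 1.83 and 2.79 in libraries 1 to 3. The level of Glul over that in the T cell-like class of the same library had its lowest value, 6.08-fold (5.89 to 6.27), in library 2. This argues against free RNA as the whole source of the Glul level in these clusters. It does not compare them with other hepatocyte-like cells, so it cannot say whether free RNA holds a part of that difference. Depth per cell is argued against as the whole source by the log2 ratios of Glul and Oat among hepatocyte-like cells of 1 quartile of UMIs, whose lowest value was 2.05 (2.04 to 2.07), for Glul in the deepest quartile, against 2.32, 3.00 and 2.33 for Glul in the others. The quartiles were taken over all libraries together, so the ratios within them can still hold a difference between libraries.

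Saa1 and Saa2 were higher in cluster 7 than in other hepatocyte-like cells. Within library 1 the log2 ratio of Saa1 was 1.58 (0.72 to 2.34) and within library 3 it was 2.73, against 5.93 in the pool. A difference between libraries is thus argued against as the whole source, but it made up part of the pooled size. Free RNA is argued against as the whole source of the Saa1 level by Saa1 in cluster 7 of library 3 lying 52.8-fold (44.2 to 63.6) above T cell-like cells of that library. This too does not compare cluster 7 with other hepatocyte-like cells.

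Genes of the cell cycle were higher in cluster 1 than in other hepatocyte-like cells. Depth per cell is argued against as the whole source by the log2 ratio of summed G2 and M phase genes within quartiles of UMIs, whose lowest value was 0.74 (0.72 to 0.76) in the deepest, against 1.39, 1.85 and 1.48 in the others. These quartiles also joined the libraries, so their ratios do not separate depth from a difference between libraries. A difference between libraries stays open: the lower of the ratios in libraries 2 and 4 was 0.34 (0.31 to 0.36), above 0 but under the bound of 0.5 set in advance, with 0.99 in library 4, 2.52 in library 3 and 0.97 in the pool.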

How the results depend on the processing

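The alternatives chosen only after the data were seen were the automatic doublet thresholds, the names without a rival rule or a minimum of cells, and the reading that sets counts under 3 to 3. The names without a rival rule or a minimum of cells left every log2 ratio of a named gene as it was. A minimum of 20 UMIs and counts under 3 set to 3 bear only on which genes pass, so they could not change a ratio. Over 3519 ratios under the other 13 alternatives, 1833 stayed within their counting interval, 1640 moved beyond it in the same direction and 46 reversed, and 329 (9.35%) fell under 2-fold or reversed. All 26 named genes of macrophage-like against Kupffer cell-like cells kept their direction in the 10 of those 13 that gave the comparison, and 15 kept a 2-fold size throughout. For the T cell-like class against NK cell-like cells these were 23 and 14 of 27 genes in 13 alternatives, and for sinusoidal against vascular endothelial cell-like cells 26 and 9 of 30 in 12. In hepatocyte-like clusters 1, 6, 7, 8, 12, 19, 20 and 23, 3 of 26, 24, 28, 12 and 29 of 30, 10 of 26, 25 of 30 and 9 of 30 genes kept a 2-fold size throughout. Between 210 and 271 of 271 list members kept their leading class. Clusters are rebuilt under several alternatives, so compared cells differ there, and a library left out or thinned cells leave fewer counts. Otherwise the cause was not tested. Depth limits what can be read in libraries 1 and 3, with medians of 1304 and 1318 UMIs per barcode, and genes with under 100 UMIs were not named.

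Log2 ratios that reversed, counts of members that moved by over 1.5 times and hepatocyte-like shares beyond their interval follow for each alternative, with some ratios that moved in the same direction. A number beside a cluster is its count of members that met both the size and library conditions, and a library left out is also left out of that condition. With the mean of each cell's CPM, cluster 19 had 15 members, and log2 ratios were 1.25 for Spink1 in cluster 1, 0.0795 for Lbr and 0.58 for Slc2a1 in cluster 19 and 0.71 for Dlk1 in cluster 23. With libraries at equal weight, 2 members were lower in macrophage-like cells, 10 lower in sinusoidal endothelial cell-like cells, cluster 8 had 45, and Dlk1 in cluster 23 stood at 4.92. With counts under 3 set to 3, 8 members were higher in the T cell-like class, and clusters 7, 8, 19 and 20 had 41, 24, 4 and 49. With cells thinned to 1000 UMIs, the hepatocyte-like share was 59.5%, 10 members were lower in sinusoidal endothelial cell-like cells, and clusters 6, 7, 12 and 20 had 33, 64, 70 and 41. Log2 ratios there were 1.03 for Spink1 in cluster 1, 0.26 for Ccl2 in cluster 20, and -0.36 for Cxcl2, 0.17 for Cyp8b1 and 2.5 for Dlk1 in cluster 23.

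At resolution 0.5 clusters 1 and 12 matched the same cluster, as did 19 and 20, so values there are of joined clusters. The share was 57.3%, clusters 1 and 19 had 128 and 64, and log2 ratios were -2.63 for Afp and -0.91 for Fabp5 in the T cell-like class and 1.41 for Lef1 and 3.67 for Spink1 in cluster 1. At resolution 2.0 the share was 49.5%, 12 members were higher in macrophage-like cells, clusters 1 and 19 had 26 and 40, and log2 ratios were 0.25 for Acaca and 0.0923 for Ass1 in sinusoidal endothelial cell-like cells and -0.0753 for Ttk in cluster 1. With the function lists kept in the clustering, the share was 46.7%, 9 members were higher in the T cell-like class, clusters 7, 8 and 19 (joined with 20) had 150, 10 and 100, and log2 ratios were -2.31 for Afp and -0.24 for Fabp5 in the T cell-like class and 0.13 for Cdca2 in cluster 8. With doublets kept, the share was 54.4%, and Afp and Fabp5 in the T cell-like class stood at -2.47 and -0.63. With automatic doublet thresholds, the share was 57.5%, they stood at -2.67 and -0.83, clusters 19 and 23 had 75 and 21, and Fabp5 and Psmb8 in cluster 23 stood at 0.66 and 0.25. With the stricter filter, the share was 62.1%, 13 members were higher in macrophage-like cells, 9 lower in the T cell-like class, clusters 1, 19 and 20 had 36, 60 and 145, and Afp and Fabp5 in the T cell-like class stood at -3.19 and -1.09.

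With each library left out in turn, the share ran from 44.5% to 59.2%, the members higher in sinusoidal endothelial cell-like cells from 3 to 9, and those of clusters 1, 7 and 19 from 10 to 54, 85 to 170 and 68 to 137. Log2 ratios ran from -1.70 to 0.0848 for Acaca, -3.66 to 0.21 for Entpd1 and -3.77 to 0.0528 for Fasn in sinusoidal endothelial cell-like cells, and from -0.26 to 1.40 for Isg15 and -0.27 to 1.90 for Tnf in the T cell-like class. In cluster 1 they ran from -0.20 to 1.33 for Aurka, -0.00383 to 1.91 for Aurkb, -0.0140 to 1.72 for Dscc1, -0.14 to 1.06 for Ndc80 and -0.15 to 1.00 for Ube2c, each lowest without library 3, and in cluster 6 from -4.64 to 0.75 for Saa1 and -4.69 to 0.44 for Saa2, each highest without library 3. In cluster 23, which was found without library 2 only, they were 1.10 for Dlk1, 1.00 for Fabp5, 0.31 for Isg15, 0.24 for Junb, 0.0404 for Psmb8 and 0.00649 for Sds. The rival rule changed no name in the reported clustering and up to 2 in others, and no minimum of cells changed 1 and up to 3.

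Some alternatives gave no value. Macrophage-like against Kupffer cell-like cells had none at resolution 0.5 or without libraries 1 or 2, and sinusoidal against vascular endothelial cell-like cells none at resolution 0.5. The clusters that matched cluster 1 with lists kept and cluster 8 at resolution 2.0 and without library 1 stayed unnamed, so no comparison was made. No cluster matched cluster 1 without library 2, cluster 6 without library 1, cluster 7 without library 3, cluster 8 with the stricter filter or without library 3, cluster 12 without library 2, cluster 19 without library 4, and cluster 23 at resolution 0.5, with lists kept, with the stricter filter or without libraries 1, 3 or 4. The alternatives planned for the comparison of weeks were not run, since that comparison could not be made.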

Other observations

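No test between libraries was made, and the genes below were picked after their values were seen. In hepatocyte-like cells of libraries 1 to 4, the values of 3 of 11 fetal liver and carcinoma genes follow. Afp stood at 1.15 CPM (0.497 to 2.27) in library 1, 394 (387 to 400.5) in library 2, 26.4 (24.0 to 29.0) in library 3 and 89.8 (86.4 to 93.2) in library 4, and H19 at 0.144, 3778, 630.0 and 3371 CPM. Igf2, a fetal growth factor, had 0 UMIs in library 1, which allows up to 0.530 CPM, and stood at 599, 26.2 and 412 CPM in libraries 2, 3 and 4. Glul stood at 743, 5607, 1338 and 10546 CPM, Saa1 at 18.1, 9.22, 3378 and 7.95 CPM and Myc at 1.73, 249.6, 23.9 and 215 CPM. Different clusters made up this class in each library, with cluster 6 holding 41.0% of all cells of library 1, cluster 1 17.5% of library 2, cluster 8 29.5% of library 3 and cluster 19 31.3% of library 4.

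In the T cell-like class, the inhibitory receptor Pdcd1 stood at 6.05 CPM (2.22 to 13.2), 114 (100.2 to 128), 8.26 (3.96 to 15.2) and 57.0 (39.0 to 80.5) in libraries 1 to 4, Tigit at 25.2, 149, 23.1 and 74.9 CPM and the naive and memory gene Tcf7 at 181, 58.5, 149 and 92.7 CPM. In vascular endothelial cell-like cells Esm1, a gene of growing vessel tips, had 0 UMIs in library 1, which allows up to 16.3 CPM, and stood at 589.6, 137 and 457 CPM in libraries 2, 3 and 4. Cluster 18 held most of this class in library 1 and cluster 11 in the others. In stellate cell- or fibroblast-like cells Acta2, the actin of contractile cells, stood at 157 CPM (118 to 204), 1009 (861 to 1175), 925 (825 to 1034) and 2896 (2674 to 3131), from 116, 37, 136 and 52 cells.

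Pairs of libraries shared 720 barcode sequences in all, which for random draws gives a list of 754265 (701127 to 812540) possible barcodes.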
